A study of Drosophila melanogaster with 23 samples.

How the data were processed

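Ovaries were dissected in buffered saline 1 to 5 days after eclosion, RNA was poly(A)-selected and fragmented for 13 minutes, and directional libraries were sequenced on an Illumina NextSeq, per the labels' protocols. Samples for the total and polysome libraries went onto polysome gradients before their RNA was isolated, per the labels' protocols. The deposited values were raw read counts per gene, which the authors made with HISAT2 2.1.0 and featureCounts 1.6.0.4 on dm6, per the submitters' processing notes. Those notes also name edgeR 3.16.5. The annotation release and the strand setting of the counting are not given in the sources used here, so genes that overlap another gene carry an uncertain value. Each of the 23 tables held 17023 FlyBase gene IDs, of which 16647 had a symbol in the reference used here and 376 did not. Gene places come from the Ensembl release 115 annotation of BDGP 6.54, whose coordinates are those of dm6. A further 8 small tables with 2 rows each accompany the polysome experiment and enter no comparison.

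Counts were tested with edgeR 4.0.16 in R 4.3.3: TMM scaling, filterByExpr by group (minimum count 10, minimum total 15), a quasi-likelihood fit and F test, and Benjamini-Hochberg adjustment over all genes tested in the comparison, with a threshold of 0.05 and no fold minimum. Fold changes are log2 from the fitted model, and the SE is the fold change divided by the root of F. CPM are counts scaled to each library's total without TMM, with an SD over the 2 libraries of a group, or given per library. Correlations across genes used log2 CPM with a prior count of 2 or the fitted fold changes. The 11 comparisons used 5 fits: hsbam 1 and 2 with the libraries labelled MSL3 RNAi and NC2b RNAi, hsbam 3 and 4 with Set2 RNAi, bam RNAi with and without the RpS19b mutation, the total and polysome libraries, and the hsbam pairs against each other. The change of the polysome to total ratio was tested as an interaction. The comparisons, the gene lists, the rule for named genes and most alternatives were chosen before the data were examined.

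The 28 gene lists cover meiosis, germline differentiation, ribosomes, chromatin regulators, somatic ovarian cells, other tissues, stress and metabolism. The lists other than X-linked genes held 908 entries. For each list the members past the threshold were counted over all genes and adjusted over the list alone. Camera from limma 3.58.1 compared each list with all other genes at a preset correlation of 0.01, adjusted over the lists of a comparison, with an estimated correlation as the alternative. At the preset value 91 list tests passed over all comparisons, and with the estimated one 0.

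Genes were named by 3 rules. The first always names the targeted genes, bam, Rbfox1, RpS19a, ord, sunn, c(3)G, c(2)M, cona, mei-W68, mei-P22 and rec. The second names the 5 largest rises and 5 largest falls among passing genes with a mean log2 CPM of at least 2 and groups that do not overlap. The third names up to 4 members with the smallest p among those passing in each list discussed. Named outside these rules, after their values were seen, were hdm, osk and Cp36, Mhc, Hsp23 and Hsp68 where their levels are given, and RpS10a, tj and Cyp4p2 in the direct comparison of the knockdowns. Where 2 of the rules name a gene it counts under both.

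Each fit was tested on simulated data with 200 changed genes. These were drawn from genes above the median level, and all genes varied independently, so recovery of genes with lower levels was not tested. For the fit of the libraries labelled MSL3 RNAi, 98% of 100 genes changed 8-fold and 14% of those changed 2-fold were recovered. The corresponding shares were 79% and 0% for Set2 RNAi, 100% and 52% for the RpS19b mutation, and 69% and 1% for the hsbam pairs. Wrong calls were 7 beside 112 right ones for the libraries labelled MSL3 RNAi, 18 beside 79 for Set2 RNAi, 18 beside 152 for the RpS19b mutation, 6 beside 70 for the hsbam pairs and 0 beside 14 for S19b RNAi in total RNA. They made up 5.9%, 18.6%, 10.6%, 7.9% and 0% of all calls, 1 simulation per fit, so 4 of the 5 shares lay above the nominal 5%. Overlaps of calls used Fisher's exact test. In addition, 100 simulated pairs of unchanged groups against the same controls gave the correlation that sharing controls brings when genes vary independently.

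Alternatives were DESeq2 size factors, library size alone, no filter on low counts, DESeq2 1.42.0, limma-voom, a 2-fold minimum, leaving out each library, a replicate block, other hsbam libraries as control, and all libraries in 1 fit. Whole ovaries, with 1 library, are given with 95% Poisson intervals. They entered that joint fit. Their ratio to bam RNAi was correlated with the fold changes and served to match genes for stage in the closing section. Genes with 3 or fewer counts in a group are given as ratios of pooled counts with an exact interval. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.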

Results

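The data were poly(A)-selected RNA sequencing counts from 23 libraries of Drosophila melanogaster ovaries dissected 1 to 5 days after eclosion. They fell into 12 groups of 2 libraries each, except whole ovaries, which had 1. The control called hsbam carried bam RNAi in the germline together with a heat-shock bam transgene. Loss of bam, the switch for cyst differentiation, keeps germ cells undifferentiated, and a pulse of bam lets them go on. The hsbam libraries were numbered 1 and 2, which served as control for the libraries labelled MSL3 RNAi and for NC2b RNAi, and 3 and 4, which served for Set2 RNAi. The libraries of each knockdown carried UAS-Dcr2 with the nos-GAL4 driver and no bam RNAi, per the labels, and whole ovaries carried the same pair of transgenes with no RNAi. A comparison with hsbam therefore differs in the handling of bam as well as in the targeted gene. A separate experiment compared bam RNAi with bam RNAi carrying an RpS19b mutation, and another took total and polysome RNA from hsbam and from S19b RNAi. The total count per library ran from 2780781 in hsbam polysome replicate 2 to 39149303 in hsbam 3. Nothing in the labels says whether the 2 libraries of a group came from separate dissections, so every p-value of a single gene measures only the spread between these libraries. The p-values of Fisher's test, of camera at its preset correlation and of the permutations in the closing section rest on variation across genes instead. Each fold change below compares 2 libraries with 2 and is on the log2 scale.

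The targeted genes were read first, because they check the labels. The gene msl-3, a chromodomain subunit of the MSL complex (chromosome 3L, 7123213 to 7125533, dm6), had 39.1 and 65.6 CPM (counts scaled to the library's total count) in the libraries labelled MSL3 RNAi. It had 32 and 38.5 CPM in hsbam 1 and 2, a fold change of 0.65 (SE 0.28), with adjusted p = 0.142 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. The direction runs against the label. Whole ovaries, also without RNAi, had 24.5 CPM of msl-3 in 1 library (95% Poisson interval 22.7 to 26.3), so neither reference shows a knockdown. Since msl-3 overlaps form3 on the opposite strand, its own count is uncertain. NC2beta, a subunit of the NC2 regulator of basal transcription (chromosome 2L, 15007813 to 15008538, antisense to THG), fell in NC2b RNAi by 1.42 (SE 0.33; adjusted p = 0.0383). Its level was 4.69 and 5.12 CPM there, against 12.2 and 16 CPM in hsbam 1 and 2. The call was lost when any 1 of hsbam 1, hsbam 2 and the NC2b RNAi libraries was left out, at NC2beta fold changes of -1.57, -1.20, -1.32 and -1.47. The fall is not shown to be particular to NC2b RNAi. NC2beta was at 6.87 and 7.78 CPM in the libraries labelled MSL3 RNAi (-0.87, SE 0.33; adjusted p = 0.106), which differed from NC2b RNAi by 0.56 (SE 0.33; adjusted p = 0.517), and at 7.1 and 11.3 CPM in Set2 RNAi and 6.25 CPM in whole ovaries. Set2, the H3K36 methyltransferase (chromosome X, 13413242 to 13421024), had 62.2 and 54.3 CPM in Set2 RNAi and 266 and 37.2 CPM in hsbam 3 and 4. These ranges overlap, and the fold change was -1.53 (SE 0.91, adjusted p = 0.415), or 0.46 without hsbam 3. Whole ovaries, with the same transgenes and no RNAi, had 240 CPM of Set2 in their 1 library (95% Poisson interval 235 to 246). In the libraries labelled MSL3 RNAi Set2 was higher than in hsbam 1 and 2 by 2.19 (SE 0.31). The hsbam pair is thus too uneven to check this label, and a knockdown of Set2 is not excluded. RpS19b, a germline-enriched paralog of the small-subunit ribosomal protein RpS19a (FBgn0039129, chromosome 3R, 23932729 to 23933530), fell in the mutant by 3.22 (SE 0.36; adjusted p = 0.0165), from 219 ± 42.5 to 22.4 ± 10.6 CPM (SD), and without bam RNAi library 1 or 2 its fold change of -3.36 or -3.10 no longer passed. In S19b RNAi it had 16.8 and 1.44 CPM in total RNA, against 39.4 and 227 CPM in hsbam. The bam transcript itself ranged from 4.61 to 173 CPM over hsbam 1 to 4 and reached 383 CPM in hsbam total replicate 1. It was 2.09 and 6.17 CPM in bam RNAi.

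The comparison of the libraries labelled MSL3 RNAi with hsbam 1 and 2 asked which germline transcripts depend on MSL3. RpS19b fell by 5.76 (SE 0.58; adjusted p = 0.00978), from 125 ± 56.2 to 2.18 ± 1.29 CPM (SD). The meiotic cohesion genes sunn and ord fell with it: sunn by 4.43 (SE 0.30), from 67.2 ± 8.26 to 2.96 ± 0.813 CPM, and ord by 4.01 (SE 0.40), from 91.4 ± 34.6 to 5.34 ± 0.41 CPM. Of the synaptonemal complex genes, cona fell by 6.01 (SE 0.89; adjusted p = 0.0108), from 108 ± 27.8 to 1.58 ± 1.63 CPM. The transverse filament gene c(3)G fell by 2.24 (SE 0.37; adjusted p = 0.0128), to 35.4 ± 2.89 from 177 ± 94.6 CPM. The resolvase partner hdm, named after its values were seen, fell by 5.70 (SE 1.07; adjusted p = 0.0168). Other members of the list of synaptonemal complex and meiotic recombination genes did not follow. Blm, the BLM helicase, rose by 2.08 (SE 0.25), while c(2)M (0.43), rec (0.72), mei-P22 (1.42) and mei-W68 (-0.11) did not pass. In all, 3 of the 22 tested members rose and 5 fell. Adjusted over the list alone, 9 rose and 6 fell. The list's median was 0.24 and its mean -0.57, so they differ in sign, and camera, which compares a list with all other genes, gave adjusted p = 0.467 (0.893 with an estimated correlation). The 8 calls became 5 without MSL3 RNAi library 1 and 1 with all 4 hsbam libraries as control. Of these genes, cona lies antisense to Vha100-4, c(3)G to Uros2, and mei-W68 shares its region with par-1. The strand setting of the counts is not given, so their values are uncertain.

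Maternal, eggshell and cell cycle genes rose in the libraries labelled MSL3 RNAi. Among oocyte patterning and maternal mRNAs, 18 of 24 rose and 0 fell over all genes, and 18 rose and 1 fell adjusted over the list alone. They included exu (3.49, SE 0.43), needed for bicoid mRNA localization, the terminal receptor tor (2.65, SE 0.28), gcl (2.27, SE 0.26) for germ cell formation, and tral (2.57, SE 0.33). Camera's adjusted p was 6.12e-12, and adjusted p = 0.686 with an estimated correlation. The posterior determinant osk, named after its values were seen, rose by 4.73 (SE 0.85; adjusted p = 0.0152), or by 4.31 with adjusted p = 0.058 without MSL3 RNAi library 1. Its level was 902 and 1570 CPM against 81.2 and 15.5 CPM in hsbam 1 and 2, but 958 CPM in hsbam 3 and 11.1 CPM in hsbam 4, so the rise rests on the control. Among genes of the female meiotic divisions, 16 of 21 rose and 0 fell, and 17 rose and 1 fell adjusted over the list alone, with Grip71 of the gamma-tubulin ring at 2.00 (SE 0.26) and the anaphase activator cort at 2.15 (SE 0.36). Among cell cycle and DNA replication genes, 24 of 34 rose and 0 fell, and 26 rose and 1 fell adjusted over the list alone. The cyclins CycA (2.67, SE 0.29) and CycB3 (2.72, SE 0.26) and the securin pim (2.53, SE 0.25) were among them. These lists had adjusted p = 1.55e-07 and 1.48e-12 by camera, and adjusted p = 0.686 each with an estimated correlation. Among cyst differentiation and oocyte specification genes, 11 of 21 rose and 3 fell, and 13 rose and 3 fell adjusted over the list alone. The deubiquitinase otu (3.04, SE 0.32) and the translational repressor bru1 (2.41, SE 0.30) rose, and bgcn, the partner of bam, fell by 3.37 (SE 0.22). This list had adjusted p = 0.00853 by camera and adjusted p = 0.686 with an estimated correlation. Since bgcn overlaps Pym on the same strand, its value is uncertain. Eggshell genes rose as well: 9 of 25 yolk, vitelline membrane and chorion genes rose and 0 fell, and 10 rose adjusted over the list alone. Cp7Fa (6.01, SE 0.93), Fcp3C (4.55, SE 0.68) and yellow-g (4.52, SE 0.78) led this list, with adjusted p = 0.000239 by camera and adjusted p = 0.686 with an estimated correlation. These counts depend on single libraries. Without hsbam 2, MSL3 RNAi library 1, NC2b RNAi library 1 or NC2b RNAi library 2, the genes of the meiotic divisions passing numbered 10, 6, 8 and 7, and those of the cell cycle 15, 15, 14 and 14. Without NC2b RNAi library 1 or 2 the cyst differentiation genes passing numbered 9 and 9. Eggshell genes passing numbered 16 without hsbam 1, 3 without MSL3 RNAi library 1 and 5 without either NC2b RNAi library, while the maternal mRNAs stayed at 13 to 18. With all 4 hsbam libraries as control 0 members of these 5 lists passed by edgeR.

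Ribosomal protein transcripts fell together in the libraries labelled MSL3 RNAi. Of 75 canonical cytoplasmic ribosomal protein genes, 71 fell and 0 rose, and 74 fell adjusted over the list alone, with a median of -1.10. RpS21 fell by 1.22 (SE 0.19) and RpLP1 by 1.34 (SE 0.22). Among germline ribosomal protein paralogs, 6 of 9 fell and 0 rose, and 7 fell adjusted over the list alone. RpS10a fell by 4.03 (SE 0.55), RpS15Ab by 1.59 (SE 0.21) and RpS14b by 1.5 (SE 0.27). The ubiquitous paralog RpS19a fell by 0.99 (SE 0.23; adjusted p = 0.0300). Of 34 genes of mitochondrial oxidative phosphorylation, 18 fell and 0 rose, and 27 fell adjusted over the list alone, among them COX7A (-1.39, SE 0.19). Camera gave adjusted p = 2.39e-21, 6.53e-06 and 4.94e-09 for the 3 lists, and adjusted p = 0.686 each with an estimated correlation. Markers of somatic cells moved too: 5 of 25 escort, cap and terminal filament markers fell and 0 rose, and 5 fell adjusted over the list alone. The Maf factor tj fell by 2.45 (SE 0.33) and the ligand Wnt4 by 2.80 (SE 0.62). For this list adjusted p = 0.000596 by camera and adjusted p = 0.707 with an estimated correlation. X-linked genes, the targets of the MSL complex in males, had a median of 0: 348 of 1715 rose and 145 fell, 365 and 155 adjusted over the list alone, with adjusted p = 0.391 by camera. Of the 71 canonical ribosomal protein calls, 15 passed without hsbam 2, 6 without MSL3 RNAi library 1, and 2 and 1 without NC2b RNAi library 1 or 2. The paralogs passing numbered 3 without hsbam 2, MSL3 RNAi library 1 or NC2b RNAi library 2. For oxidative phosphorylation the count was 7 without hsbam 1, 3 and 10 without MSL3 RNAi library 1 or 2, and 4 without either NC2b RNAi library. For the escort, cap and terminal filament markers it was 2 without hsbam 2, 3 and 13 without MSL3 RNAi library 1 or 2, and 2 without either NC2b RNAi library. X-linked genes passing numbered 242 without hsbam 2, 196 without MSL3 RNAi library 1, and 188 and 184 without NC2b RNAi library 1 or 2. With all 4 hsbam libraries as control the counts of these 5 lists were 0, 1, 0, 0 and 2 by edgeR.

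Over all 10180 tested genes, 1710 rose and 863 fell, 2573 in all, by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment at 0.05. Of these, 1239 rose and 671 fell at least 2-fold. The genes with the largest rises were CG15571 (6.81, SE 0.93), CG12716 (6.64, SE 1.20), CG15820 (6.37, SE 0.91), Cp7Fa and CR45458 (5.74, SE 0.47, but -0.75 with hsbam 3 and 4 as control). The largest falls were those of CG14301 (-9.16, SE 1.68), Cyp4p2 (-8.00, SE 0.71), NANS (-6.35, SE 0.99), CG31683 (-6.21, SE 1.32) and CG3251 (-6.12, SE 0.68). CG14301, antisense to qin, rests on the control: it had 18.7 and 392 CPM in hsbam 1 and 2 but 1.1 and 2.43 CPM in hsbam 3 and 4. With hsbam 3 and 4 as control 0 genes passed, with all 4 hsbam libraries 18, and with all 23 libraries in 1 fit 0. The count was 1277 without hsbam 2, 1073 without MSL3 RNAi library 1, and 987 and 975 without NC2b RNAi library 1 or 2, which share the fit.

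**Figure D1:**
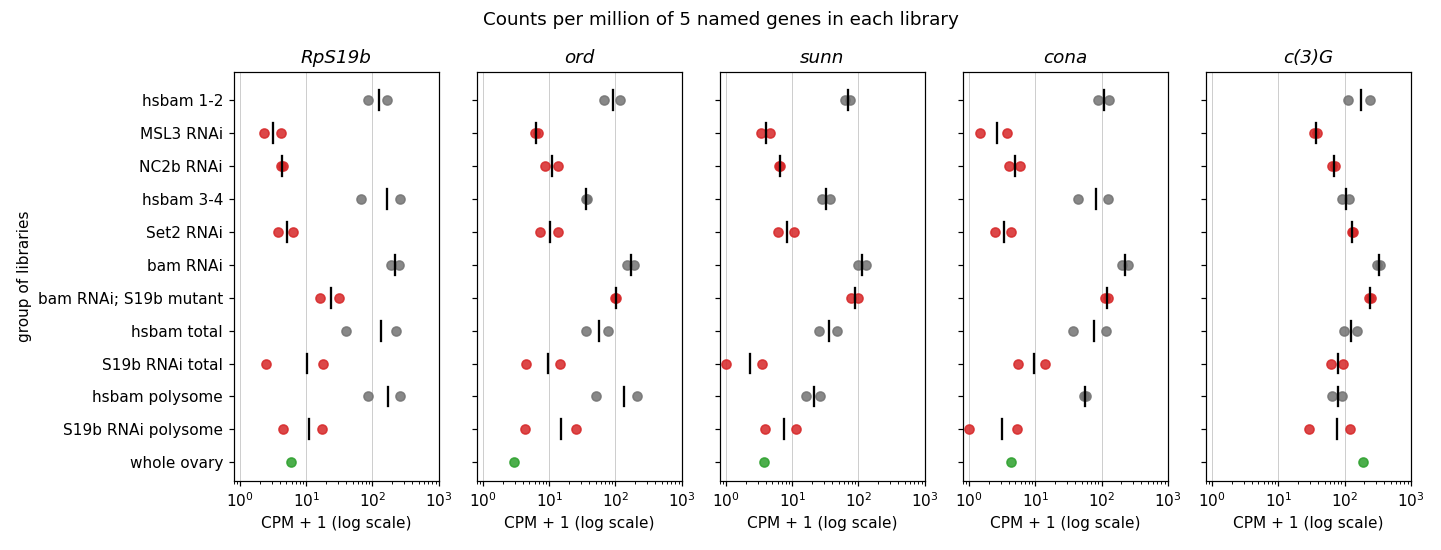
CPM plus 1 (log axis) of RpS19b, ord, sunn, cona and c(3)G, 1 point per library and a bar at each group mean, with controls in grey, knockdowns and mutant in red and whole ovaries in green. RpS19b lies between 1.26 and 5.26 CPM in the libraries labelled MSL3 RNAi, in NC2b RNAi and in Set2 RNAi, and between 67.3 and 259 CPM in hsbam 1 to 4.

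NC2b RNAi, compared with the same control libraries, asked whether NC2b acts on the same transcripts. RpS19b fell by 5.15 (SE 0.56; adjusted p = 0.0166), from 125 ± 56.2 to 3.27 ± 0.178 CPM (SD). The cohesion genes sunn and ord fell by 3.52 (SE 0.29) and 3.09 (SE 0.38), to 5.47 ± 0.152 and 10 ± 3.42 CPM. The synaptonemal complex gene cona fell by 4.69 (SE 0.84; adjusted p = 0.0215), whereas c(3)G at -1.28 (SE 0.36) had adjusted p = 0.0591. The gene hdm fell by 4.98 (SE 1.04). Of the 22 synaptonemal complex and meiotic recombination genes, 3 rose, among them Blm (1.84, SE 0.24), and 4 fell, and adjusted over the list alone 6 rose and 6 fell. Camera gave this list adjusted p = 0.601 (0.856 with an estimated correlation). The 7 calls became 3 without hsbam 2 and 0 without either NC2b RNAi library.

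The later gene groups rose in NC2b RNAi too. Among oocyte patterning and maternal mRNAs, 18 of 24 rose and 0 fell, and 19 rose adjusted over the list alone: exu (3.80, SE 0.44), the RNA helicase me31B (2.81, SE 0.32), tral (2.84, SE 0.33) and gcl (2.44, SE 0.26). Among genes of the female meiotic divisions 16 of 21 rose and 0 fell (16 and 1 adjusted over the list alone), with cort at 2.42 (SE 0.36). Among cell cycle and DNA replication genes 23 of 34 rose and 0 fell (24 and 1 adjusted over the list alone), with CycA at 2.80 (SE 0.29). Among yolk, vitelline membrane and chorion genes 10 of 25 rose and 0 fell (12 adjusted over the list alone), with Fcp3C at 6.41 (SE 0.74), Cp7Fa at 6.38 (SE 0.95) and Vm32E at 3.34 (SE 0.45). Camera gave these 4 lists adjusted p = 1.14e-13, 2.25e-07, 8.57e-12 and 1.56e-09, and adjusted p = 0.724 each with an estimated correlation. Of the cyst differentiation and oocyte specification genes 10 of 21 rose and 2 fell (13 and 6 adjusted over the list alone). The RNA-binding protein gene orb (2.54, SE 0.32), otu (3.29, SE 0.32) and bru1 (2.77, SE 0.31) rose, and bgcn, which overlaps Pym, fell by 5.07 (SE 0.24). This list had adjusted p = 0.0244 by camera and adjusted p = 0.724 with an estimated correlation. Without either NC2b RNAi library 0 members of these 5 lists passed by edgeR, and 0 with all 4 hsbam libraries as control. Without hsbam 1 the count was 9 for the meiotic divisions, 12 for the cell cycle and 16 for eggshell genes, and without hsbam 2 it was 6 for each of the meiotic divisions, the cell cycle and cyst differentiation.

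Of 25 escort, cap and terminal filament markers 7 fell and 0 rose in NC2b RNAi (13 fell adjusted over the list alone), with Wnt4 at -3.29 (SE 0.64). The posterior compartment gene en had 37 counts in hsbam 1 and 2 and 0 in NC2b RNAi. The exact 95% lower limit on this ratio was 9.33-fold, and against an assumed floor of 3 counts over the group the ratio would be 12.1-fold. Of the germline ribosomal protein paralogs 3 of 9 fell over all genes and adjusted over the list alone, with RpS14b at -1.19 (SE 0.27). Of the 75 canonical ribosomal protein genes, with a median of -0.55, 4 fell by edgeR (0 adjusted over the list alone) and 34 passed by DESeq2. Of the 34 oxidative phosphorylation genes 10 fell (11 adjusted over the list alone). For these 4 lists camera gave adjusted p = 1.05e-05, 0.0364, 8.46e-07 and 1.02e-05, and adjusted p = 0.724 each with an estimated correlation. Muscle sheath genes had a median of -1.79 with 0 of 24 passing (camera, adjusted p = 0.000133; adjusted p = 0.724 with an estimated correlation). The myosin gene Mhc was at 5130 and 1370 CPM in hsbam 1 and 2 and at 796 and 792 CPM in NC2b RNAi. Of 22 fat body and hemocyte genes, with a median of -1.88, the collagen genes vkg (-2.09, SE 0.49) and Col4a1 (-2.14, SE 0.52) fell and srp (0.77, SE 0.20) rose, and 0 passed adjusted over the list alone. These calls went to 0 without hsbam 1, hsbam 2 or either NC2b RNAi library, and to 5 without either library labelled MSL3 RNAi. The list had adjusted p = 0.0244 by camera and adjusted p = 0.812 with an estimated correlation. Gut and digestive enzyme genes had the largest median of the lists, 4.41, with 0 of 18 passing by edgeR and 1 by DESeq2 (camera, adjusted p = 0.417; adjusted p = 0.857 with an estimated correlation). Without either NC2b RNAi library 0 members of these lists passed by edgeR. Without hsbam 1 or 2 the count was 3 and 0 for the escort, cap and terminal filament markers and 1 and 0 for oxidative phosphorylation. Without hsbam 2 it was 0 for canonical ribosomal proteins, 1 for the paralogs and 2 for muscle sheath genes. Without either library labelled MSL3 RNAi it was 14 for the escort, cap and terminal filament markers, 12 for canonical ribosomal proteins and 4 for muscle sheath genes.

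Over all 10180 genes, 1436 rose and 461 fell in NC2b RNAi, 1897 in all, by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. The largest rises were those of CG15571 (7.28, SE 0.95), CG12716 (7.19, SE 1.23), CG15820 (6.72, SE 0.92), CG13737 (6.43, SE 0.85) and Fcp3C. The largest falls were those of CG14301 (-7.65, SE 1.55), Trf5 (-7.26, SE 0.89), the testis regulator aly (-5.79, SE 0.74), CG14932 (-5.62, SE 0.50) and CG3251 (-5.36, SE 0.65). Both NC2b RNAi libraries were needed: 0 genes passed without library 1 or without library 2. The count was 1176 without hsbam 1, 370 without hsbam 2, 2857 without MSL3 RNAi library 2, 3236 with DESeq2, 3 with all 4 hsbam libraries as control, 0 with hsbam 3 and 4, and 0 with all 23 libraries in 1 fit.

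**Figure D2:**
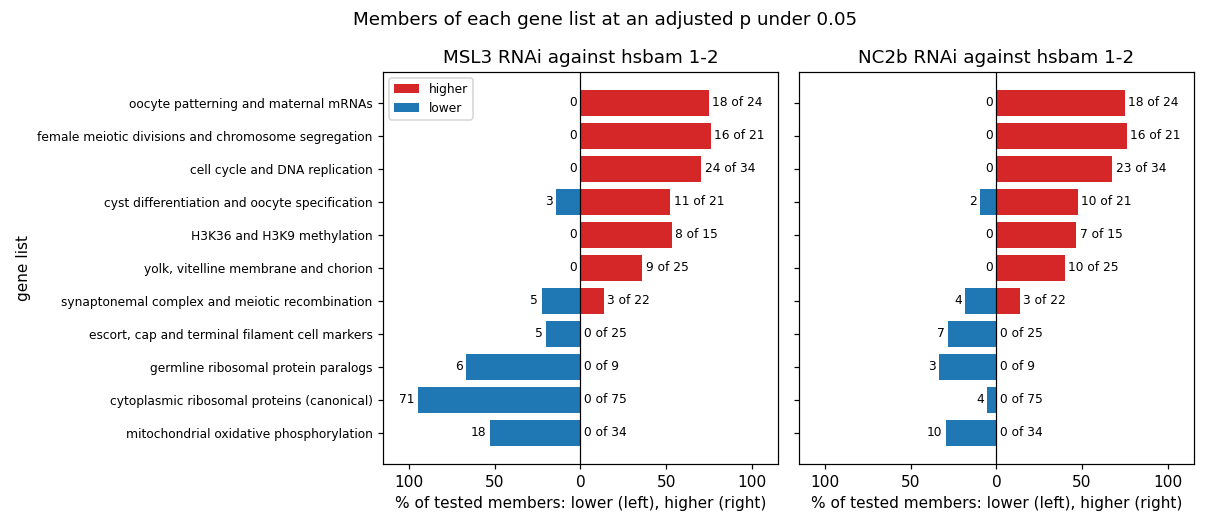
Share (%) of the tested members of 11 gene lists that passed an adjusted p of 0.05, bars to the right for higher and to the left for lower, in the libraries labelled MSL3 RNAi and in NC2b RNAi, with the counts printed. Canonical ribosomal proteins have 71 of 75 members lower in the first comparison and 4 in the second. Their medians were -1.1 and -0.55, and 0 members passed by edgeR in the direct comparison of the knockdowns.

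The calls of the libraries labelled MSL3 RNAi and of NC2b RNAi overlapped. Both comparisons called 1285 genes higher, where independent calls would give 241.2, and 305 lower, where they would give 39.1 (Fisher's exact test, two-sided, p = 1.54e-229 for the lower genes). The comparisons share hsbam 1 and 2, which alone makes their fold changes correlate. Across genes, which are not independent replicates, r was 0.78 against 0.50 (0.46 to 0.54) in 100 simulations of unchanged groups against those controls. The covariance was 1.89 against 0.27. The simulations drew each gene independently, so they hold no shift common to many genes, in the controls or through the handling of bam. Fisher's test assumes independent genes too. Neither therefore shows an overlap beyond what the same controls and the same difference in bam bring. With separate control pairs for each comparison r was 0.46 and 0.49. In the direct test RpS10a, at 2.68 ± 1.04 CPM (SD) in the libraries labelled MSL3 RNAi and 37.9 ± 22.4 CPM in NC2b RNAi, differed by -3.85 (SE 0.54; adjusted p = 0.291, and 0.00402 adjusted over the list alone). The somatic marker tj differed by -1.96 (SE 0.32; adjusted p = 0.291, and 0.0258 adjusted over the list alone), and Cyp4p2 by -8.95 (SE 0.73; adjusted p = 0.154, and 0.00214 adjusted over the list alone). RpS10a, tj and Cyp4p2 were chosen after their values were seen, and adjustment over the list alone does not allow for choosing gene or list. Across genes, the difference between the knockdowns followed the ratio of whole ovary to bam RNAi at r = -0.42, so stage may enter it. Of the 9 germline ribosomal protein paralogs 4 were lower adjusted over the list alone (camera, adjusted p = 1.34e-06; adjusted p = 0.884 with an estimated correlation). The canonical ribosomal proteins had adjusted p = 6.97e-22, and adjusted p = 0.884 with an estimated correlation. By edgeR 0 of 10180 genes passed, 1178 had an unadjusted p under 0.05, DESeq2 called 227 and limma-voom 0. Without MSL3 RNAi library 1 the count was 30, and without hsbam 1 or hsbam 2 it was 1.

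Set2 RNAi was compared with hsbam 3 and 4 to ask whether the H3K36 methyltransferase acts on the same germline transcripts. RpS19b was 4.02 ± 1.76 CPM (SD) against 163 ± 136 CPM, a fold change of -5.53 (SE 0.88; adjusted p = 0.0611, and 0.0139 adjusted over the list alone). The meiotic genes cona (-5.33, SE 0.77), sunn (-2.31, SE 0.44) and ord (-2.12, SE 0.42) had adjusted p = 0.0595, 0.0791 and 0.0814, and 0.0225, 0.0294 and 0.0294 adjusted over the list alone. Their levels were 2.33 ± 1.28, 7.26 ± 3.24 and 9.24 ± 4.4 CPM. The transverse filament gene c(3)G was 131 ± 5.88 against 103 ± 17.1 CPM, a fold change of 0.17 (SE 0.34; adjusted p = 0.782), or -0.48 against hsbam 1 and 2. The list of synaptonemal complex and meiotic recombination genes had 0 of 22 members passing over all genes and 4 lower adjusted over the list alone. In a joint fit of both experiments, chosen after seeing the data, the effect on c(3)G in the libraries labelled MSL3 RNAi differed from that in Set2 RNAi by -2.51 (SE 0.57), with adjusted p = 0.265.

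Muscle, fat body and heat shock genes were lower in Set2 RNAi. All 24 tested muscle sheath genes were lower adjusted over the list alone and 0 over all genes, with Mhc at -4.39 (adjusted p = 0.00309 over the list alone; 223 ± 9.5 against 4150 ± 533 CPM). Of 18 heat shock genes 13 were lower adjusted over the list alone. Hsp68, a chaperone induced by heat, had 16 ± 4.54 against 2100 ± 338 CPM. Of 21 fat body and hemocyte genes 11 were lower adjusted over the list alone. Camera gave these 3 lists adjusted p = 8.04e-19, 2.44e-11 and 2.98e-08, and adjusted p = 0.769, 0.769 and 0.882 with an estimated correlation. Other lists were low as well. Of 90 glutathione S-transferase and cytochrome P450 genes, with a median of -1.40, 24 were lower adjusted over the list alone (camera, adjusted p = 5.74e-06; adjusted p = 0.960 with an estimated correlation). The gut and digestive enzyme list had only 3 tested members and a median of -5.02, with 2 lower adjusted over the list alone (camera, adjusted p = 0.122). Antimicrobial genes had a median of -1.53, with 3 of 20 higher and 2 lower adjusted over the list alone (camera, adjusted p = 0.940). Yolk, vitelline membrane and chorion genes were higher as a list by camera (adjusted p = 1.79e-07; adjusted p = 0.960 with an estimated correlation), as were cell cycle and DNA replication genes (adjusted p = 5.74e-06; adjusted p = 0.960 with an estimated correlation). Of the genes that rose in the libraries labelled MSL3 RNAi, 1573 of 1698 had a positive fold change in Set2 RNAi (camera, p = 3.04e-22; p = 0.359 with an estimated correlation). Of those that fell, 599 of 778 had a negative one (camera, p = 1.22e-05; p = 0.503 with an estimated correlation). In S19b RNAi total RNA 852 of 1697 such higher genes were positive and 483 of 777 lower genes negative. With the RpS19b mutation 768 of 1679 and 512 of 829 were. Across genes, fold changes followed the ratio of whole ovary to bam RNAi at r = 0.42 in the libraries labelled MSL3 RNAi, 0.63 in NC2b RNAi and 0.57 in Set2 RNAi. A common sign can thus come from stage or the handling of bam as well as from the targeted genes. For Set2 RNAi 0 of 9313 genes passed by edgeR, with 1972 at an unadjusted p under 0.05 and a smallest adjusted p of 0.0565. DESeq2 called 1338 and limma-voom 0. The count was 5661 without hsbam 3, 2454 without hsbam 4, 86 and 12 without Set2 RNAi library 1 or 2, 849 with no filter on low counts, 637 with all 4 hsbam libraries as control and 3463 with hsbam 1 and 2. List members passing over all genes, 0 in each list here, numbered up to 57 without hsbam 3 and up to 36 without hsbam 4. Muscle sheath genes passing numbered 22 without either of them and heat shock genes 16 and 15, and heat shock genes 3 and 1 without Set2 RNAi library 1 or 2.

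The RpS19b mutation in a bam RNAi background asked what RpS19b does in undifferentiated germ cells. Besides RpS19b itself, the largest falls were those of Syt4, a synaptotagmin (-4.51, SE 0.50), the cuticle gene Cpr47Ee (-4.11, SE 0.51), the heat shock gene Hsp70Bc (-2.59, SE 0.52) and the secreted receptor decoy Sdr (-2.52, SE 0.31). Among the meiotic genes cona fell by 0.87 (SE 0.19, adjusted p = 0.0433), from 227 ± 35.4 to 119 ± 7.65 CPM (SD), a call that needed both bam RNAi libraries. The values of ord (-0.70, SE 0.18; adjusted p = 0.0657), sunn (-0.30, SE 0.20), c(3)G (-0.39, SE 0.18), Rbfox1 (0.02, SE 0.18) and RpS19a (-0.09, SE 0.21) did not pass. Of the 22 tested synaptonemal complex and meiotic recombination genes 1 fell, and 0 passed adjusted over the list alone (camera, adjusted p = 0.000263; adjusted p = 0.440 with an estimated correlation). The posterior determinant osk rose by 4.19 (SE 0.30; adjusted p = 0.00437), from 5.94 ± 0.181 to 103 ± 28 CPM; it overlaps lncRNA:osk on the same strand.

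Muscle and fat body markers rose in the RpS19b mutant. Of 23 muscle sheath genes 18 rose and 0 fell, and 22 rose adjusted over the list alone, with the troponin gene TpnC47D at 3.71 (SE 0.28), the titin-like bt at 2.1 (SE 0.30) and Mhc at 1.59 (SE 0.32). Of 19 fat body and hemocyte genes 9 rose and 0 fell, and 17 rose adjusted over the list alone: the lipophorin apolpp (2.44, SE 0.28), the prophenoloxidase PPO2 (2.54, SE 0.30) and the phagocytic receptor NimC1 (3.61, SE 0.49). Camera gave these lists adjusted p = 6.08e-24 and 6.67e-15, and adjusted p = 0.432 each with an estimated correlation. Of 22 yolk, vitelline membrane and chorion genes 4 rose, among them Yp2 (1.89, SE 0.28) and Yp3 (1.90, SE 0.27), and 9 rose adjusted over the list alone (camera, adjusted p = 0.00149; adjusted p = 0.525 with an estimated correlation). Of 18 heat shock genes 4 fell, and 8 fell adjusted over the list alone (camera, adjusted p = 1.30e-05; adjusted p = 0.432 with an estimated correlation). Hsp70Bb fell by 1.86 (SE 0.26), though the Hsp70 copies are near-identical and their reads cannot be assigned with certainty. Of 16 antimicrobial and immune genes 3 rose and 1 fell, and 5 rose and 1 fell adjusted over the list alone (camera, adjusted p = 0.0157; adjusted p = 0.440 with an estimated correlation). BomS3 rose by 4.34 (SE 0.73) and BomS2 by 3.65 (SE 0.62). Mtk, with 167 counts against 2, was higher by a ratio of 80.1 (95% counting interval 21.8 to 667), and TotC, with 1 count against 67, lower by 69.8 (12.1 to 2800). Without either bam RNAi library 0 members of these 5 lists passed by edgeR. Without mutant library 1 the count was 16 for fat body, 8 for heat shock and 7 for antimicrobial genes, and without mutant library 2 it was 15 for yolk, vitelline membrane and chorion genes. The chorion gene Cp36, chosen after its values were seen, was at 213 CPM in mutant library 1 and 0.607 CPM in library 2.

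Over all 9595 genes, 530 rose and 58 fell with the RpS19b mutation, 588 in all, by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. The genes with the largest rises had 2 or 3 counts in bam RNAi, so their ratios of pooled counts are given with 95% counting intervals. The ratio was 555 (190 to 2700) for kumpel, 464 (128 to 3840) for Nplp3, 379 (105 to 3130) for Osi19, 316 (108 to 1530) for Cyp4p2 and 189 (64.5 to 921) for SPH93. The count of genes was 2 without bam RNAi library 1, 1 without bam RNAi library 2 and 1314 without mutant library 1. It was 1152 with DESeq2, 1426 with no filter on low counts, 2150 with the replicate number as a block and 0 with all 23 libraries in 1 fit.

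The total and polysome libraries asked whether S19b knockdown changes which mRNAs are translated, with Rbfox1, a splicing factor and translational regulator of cyst differentiation, as the gene of interest. Rbfox1 was 157 ± 110 CPM (SD) in hsbam total RNA and 113 ± 84.4 CPM in S19b RNAi total RNA, a fold change of -0.57 (SE 1.12). In polysome RNA it was 169 ± 162 and 112 ± 127 CPM (-1.03, SE 1.13). The change of its polysome to total ratio was -0.46 (SE 1.59; adjusted p = 1.00) and ran from -2.80 to 1.68 as each library was left out, so at this spread neither a rise nor a fall of Rbfox1 was detectable. RpS19b had a fold change of -3.98 (SE 1.37) in total and -4.52 (SE 1.41) in polysome RNA, with unadjusted p = 0.0149 and 0.00864 and adjusted p = 1.00 and 0.989. Meiotic genes in total RNA were at -2.80 (SE 1.21) for ord, -4.95 (SE 1.97) for sunn, -3.25 (SE 1.52) for cona and -0.77 (SE 0.76) for c(3)G, and bam was at -3.56 (SE 1.14). None of these passed over all genes.

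Heat shock genes separated the S19b RNAi libraries from hsbam. Hsp23 was 9690 ± 4650 CPM (SD) in hsbam total RNA against 376 ± 361 CPM, and Hsp68 was 1650 ± 280 against 73.6 ± 20.3 CPM. Of the 18 tested members 8 were lower in total and 9 in polysome RNA adjusted over the list alone, and 0 over all genes, or 6 in polysome RNA without hsbam polysome replicate 1 (camera, adjusted p = 1.25e-27 and 9.41e-23; adjusted p = 0.172 and 0.260 with an estimated correlation). Yolk, vitelline membrane and chorion genes were higher as a list in total RNA (camera, adjusted p = 2.84e-14; adjusted p = 0.557 with an estimated correlation). Digestive enzymes of the gut were higher as a list too (camera, adjusted p = 7.00e-10; adjusted p = 0.863 with an estimated correlation).

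In the polysome experiment edgeR called 0 of 9688 genes in each of the 5 comparisons. Unadjusted p was under 0.05 for 170 genes in total RNA, 320 in polysome RNA, 5 for the ratio between them, 42 for polysome against total RNA in hsbam and 5 in S19b RNAi. DESeq2 called 45 genes in total and 118 in polysome RNA and limma-voom 1 and 0; both called 0 in the other comparisons. Without hsbam polysome replicate 1, 722 genes passed in polysome RNA and 460 for polysome against total RNA in hsbam. A block on replicate number within genotype, a pairing the labels do not state, gave 83 genes in total and 194 in polysome RNA. It gave 8 and 1 for polysome against total RNA in hsbam and in S19b RNAi. In simulated data for total RNA, 14% of 100 genes changed 8-fold were recovered and 0% of those changed 2-fold.

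The hsbam pairs of the 2 experiments were compared with each other. Their log2 CPM correlated at 0.847 to 0.867 across the pairs, at 0.914 between hsbam 1 and 2 and at 0.772 between hsbam 3 and 4, so the pairs did not part overall. Hsp23 was 172 and 170 CPM in hsbam 1 and 2 and 8250 and 18400 CPM in hsbam 3 and 4, a fold change of 6.49 (SE 0.80; adjusted p = 0.802). Adjusted over the list alone, 4 heat shock genes were higher in hsbam 3 and 4, and over all genes 0, or 1 and 4 without hsbam 1 or 2 (camera, adjusted p = 4.42e-18; adjusted p = 0.879 with an estimated correlation). The maternal mRNA osk was 81.2, 15.5, 958 and 11.1 CPM in hsbam 1 to 4, so it varied within each pair as well. By edgeR 0 of 10031 genes passed and 595 had an unadjusted p under 0.05, while DESeq2 called 128 and limma-voom 0. Without hsbam 1 or hsbam 2 the count was 26 or 47.

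**Figure D3:**
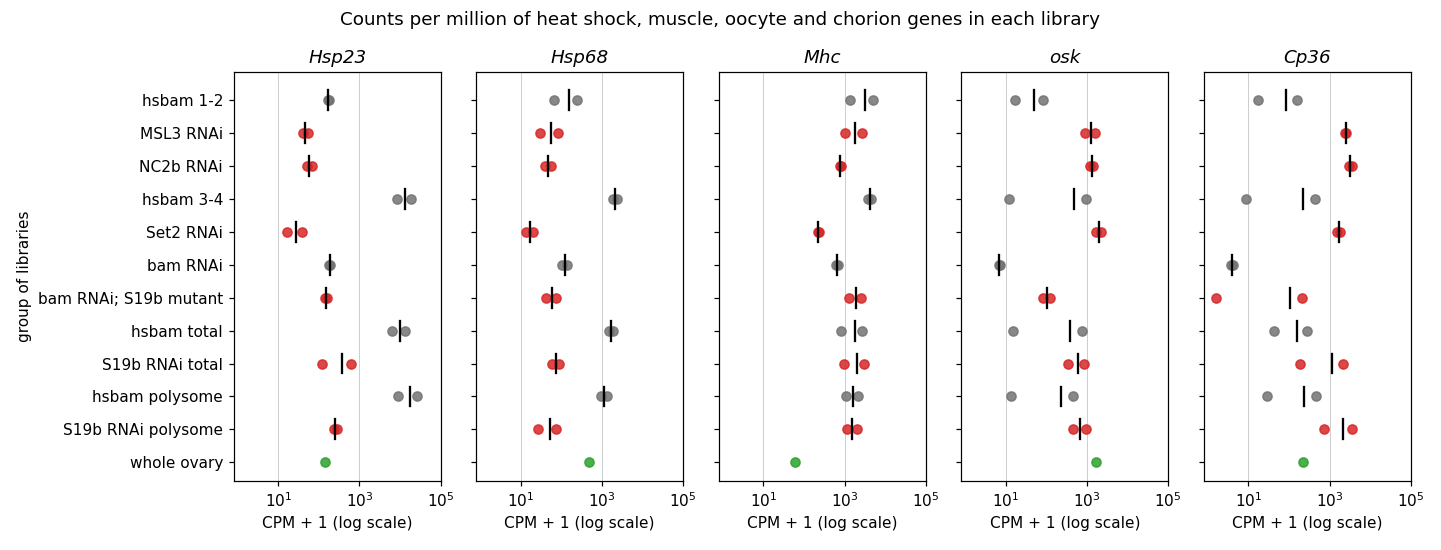
CPM plus 1 (log axis) of Hsp23, Hsp68, Mhc, osk and Cp36, 1 point per library and a bar at each group mean, with controls in grey, knockdowns and mutant in red and whole ovaries in green. Hsp23 is 8250 and 18400 CPM in hsbam 3 and 4, against 172 and 170 CPM in hsbam 1 and 2.

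Whole ovaries were a single library meant as a reference for developmental stage. RpS19b had 4.9 CPM there (95% exact Poisson interval 4.14 to 5.75), ord 1.89 (1.43 to 2.44), sunn 2.75 (2.19 to 3.4) and cona 3.21 (2.6 to 3.91). In the same library c(3)G had 187 CPM (182 to 191) and osk 1680 CPM (1670 to 1700). These intervals, like the floors and counting ratios above, cover counting error only. The correlation across genes of log2 CPM with whole ovaries was 0.932 and 0.913 in Set2 RNAi, 0.855 and 0.873 in NC2b RNAi, and 0.819 and 0.707 in libraries labelled MSL3 RNAi 1 and 2. It was 0.665, 0.739, 0.808 and 0.575 in hsbam 1 to 4, 0.883 and 0.638 in hsbam total RNA, and 0.774 and 0.799 in bam RNAi. Both NC2b RNAi libraries thus lay above their own controls, hsbam 1 and 2, and of all controls only hsbam total replicate 1 (0.883) lay higher. The libraries labelled MSL3 RNAi overlapped hsbam 1 and 2. A stage difference between NC2b RNAi and its controls is therefore not excluded, though the correlation did not part these knockdowns from all control libraries. The level of osk was 902 to 2190 CPM over the 6 libraries labelled MSL3, NC2b or Set2 RNAi.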

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

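The joint fit of the MSL3 and Set2 experiments is among the tests chosen only after the result was seen. In it 2 of 10418 genes had effects that differed between the libraries labelled MSL3 RNAi and Set2 RNAi, with 1393 at an unadjusted p under 0.05. The effect on CG14346 differed by -7.44 (SE 0.51; adjusted p = 0.00998 by edgeR). Its level was 14.2 ± 1.04 CPM (SD, 2 libraries) in hsbam 1 and 2 and 1.25 ± 0.101 CPM in the libraries labelled MSL3 RNAi, against 2.27 ± 0.394 CPM in hsbam 3 and 4 and 38.9 ± 4.9 CPM in Set2 RNAi. The effect on gNacalpha differed by -7.23 (SE 0.66; adjusted p = 0.0383 by edgeR), with 45.4 ± 17.8 and 3.37 ± 0.864 CPM in the first pair of groups and 6.99 ± 2.98 and 86.3 ± 12.6 CPM in the second. In both genes the levels in hsbam 1 and 2 did not overlap those in hsbam 3 and 4, so the control libraries enter the difference.

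The 8 small tables of the polysome experiment hold 1 row under the gene ID of Rbfox1 and 1 row without a name. The small tables carry the string cytovnuc in their names, which may stand for cytoplasmic against nuclear. What each row counts is not stated. The row under the Rbfox1 ID held 56 and 15 in S19b RNAi polysome replicates 1 and 2, and 14 and 0 in hsbam polysome replicates 1 and 2. The total counts of these 4 libraries were 8149989, 13683343, 13865679 and 2780781, so 15 and 14 are nearly equal for their depth. In total RNA the row held 0 and 7 in S19b RNAi and 5 and 0 in hsbam. The row without a name held 8 and 2 in hsbam polysome and 9 and 17 in hsbam total RNA, against 0 and 0 in S19b RNAi polysome and 0 and 1 in S19b RNAi total RNA. No explanation was tested, and no biological one can be set against it while the content of the rows is unknown.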

How the results depend on the processing

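The tests with crossed replicate numbers were chosen only after the result was seen. Counts of genes are given as totals. With DESeq2 size factors, library size alone or a 2-fold minimum, all counts of genes stayed within 1.5 times their values. So did the counts by limma-voom, with 1 exception, 1 gene instead of 0 for S19b RNAi in total RNA. Library size alone moved the median of all genes to -0.17 for the libraries labelled MSL3 RNAi, -0.19 for NC2b RNAi and 0.21 for Set2 RNAi, and turned the median of mitochondrial ribosomal proteins in NC2b RNAi from 0.02 to -0.08 and that of antimicrobial genes there from 0.04 to -0.05. In Set2 RNAi it turned the median of early follicle markers from -0.11 to 0.06 and that of translation factors from -0.04 to 0.13. Of 160 named gene values, DESeq2 size factors kept 156, limma-voom 147 and DESeq2 143 in direction and side of the threshold. All 23 libraries in 1 fit kept 30 of them, 7 passed newly and the rest no longer passed. With all 4 hsbam libraries as control 13 of 109 were kept, 90 no longer passed and 1 turned sign, and with the other hsbam pair 7 of 108 were kept, 92 no longer passed and 3 turned sign. Of 58 counts of list members, 31 moved by over 1.5 times with DESeq2, 20 with no filter, 6 with limma-voom and 48 with all 23 libraries in 1 fit. With all 4 hsbam libraries as control 41 of 44 moved and with the other hsbam pair 42 of 44. Leaving out 1 library at a time moved 165 of 322. Where the cause of a change below does not follow from how the setting is built, the cause was not tested.

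With no filter on low counts, which tests more genes, the count was 2 for the libraries labelled MSL3 RNAi against NC2b RNAi, 849 for Set2 RNAi, 1426 for the RpS19b mutation, 43 and 67 for S19b RNAi in total and polysome RNA, 1 for the polysome to total ratio and 1 for the hsbam pairs. With DESeq2 it was 3236 for NC2b RNAi, 227 for the direct comparison, 1338 for Set2 RNAi, 1152 for the RpS19b mutation, 45 and 118 for S19b RNAi in total and polysome RNA, and 128 for the hsbam pairs. With all 4 hsbam libraries as control it was 18 for the libraries labelled MSL3 RNAi, 3 for NC2b RNAi and 637 for Set2 RNAi, and with the other hsbam pair 0, 0 and 3463. With all 23 libraries in 1 fit, where the spread of every group enters, it was 0 for the libraries labelled MSL3 RNAi, 0 for NC2b RNAi, 95 for Set2 RNAi, 0 for the RpS19b mutation, 8 and 19 for S19b RNAi in total and polysome RNA, and 3 for the hsbam pairs. A polysome to total ratio differing by more than 2 SD, with no test, was found for 568 genes. List tests passed 91 times with camera's preset correlation, 0 times with an estimated correlation and 15 times with fry, which asks another question.

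The labels do not say that replicate numbers mark shared preparations, and each group holds 2. The deviations of same-numbered libraries correlated at -0.127 between hsbam and the libraries labelled MSL3 RNAi, 0.244 between hsbam and NC2b RNAi, -0.157 between these knockdowns and 0.395 between bam RNAi and the RpS19b mutant. The values were 0.411 and 0.432 between total and polysome RNA within hsbam and S19b RNAi, and -0.514 and -0.298 between the genotypes, so they do not settle which libraries are paired. With the replicate number as a block, set within genotype in the polysome experiment, the count was 2150 for the RpS19b mutation, 83 and 194 for S19b RNAi in total and polysome RNA, and 8 and 1 for polysome against total RNA in hsbam and in S19b RNAi. It stayed within 1.5 times for the libraries labelled MSL3 RNAi (1923), NC2b RNAi (1266), the direct comparison (0) and the ratio (0). With crossed numbers, a block chosen from the data, S19b RNAi gave 8 and 15 genes in total and polysome RNA. Set2 RNAi and hsbam 3 and 4 share no replicate numbers with each other, nor do the hsbam pairs, so no block could be fitted for them.

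Leaving out 1 library at a time, with the lone library assumed to vary like the others, gave 975 to 2812 genes for the libraries labelled MSL3 RNAi, 0 to 2857 for NC2b RNAi, 0 to 30 for the direct comparison, 12 to 5661 for Set2 RNAi and 1 to 1314 for the RpS19b mutation. It gave 0 to 722 for S19b RNAi in polysome RNA, 0 to 460 for polysome against total RNA in hsbam and 0 to 47 for the hsbam pairs. The low end for NC2b RNAi came without either of its libraries, and that for the RpS19b mutation without bam RNAi library 2.

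Some fold changes turned sign. With the other hsbam pair as control CR45458 was -0.75 and c(2)M -0.10 in the libraries labelled MSL3 RNAi, and c(3)G was -0.48 in Set2 RNAi. With all 4 hsbam libraries c(3)G was -0.16 there. For Rbfox1 with the RpS19b mutation the value was -0.008 with DESeq2 size factors, -0.032 with library size alone and -0.008 with DESeq2. For Rbfox1 the polysome to total ratio was 0.10 with limma-voom. Leaving out 1 library gave ranges of -0.64 to 0.33 for mei-W68 in the libraries labelled MSL3 RNAi, -2.33 to 0.46 for Set2 and -0.01 to 0.38 for c(3)G in Set2 RNAi, and -0.10 to 0.10 for Rbfox1 with the RpS19b mutation. For Rbfox1 in S19b RNAi the ranges were -1.72 to 0.52 in total RNA, -3.37 to 1.11 in polysome RNA and -2.80 to 1.68 for the ratio.

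The spread between libraries set what was detectable: the biological coefficient of variation was 0.384 in the fit of the libraries labelled MSL3 RNAi, 0.451 for Set2 RNAi, 0.264 for the RpS19b mutation and 0.914 in the polysome experiment, whose smallest library had 2780781 counts.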

Other observations

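All of the tests of explanations below were chosen only after the result was seen. Among lists of chromatin genes in the knockdowns that share hsbam 1 and 2, camera passed that of H3K36 and H3K9 methylation at the preset correlation. Of its 15 genes, 8 rose and 0 fell in the libraries labelled MSL3 RNAi (9 and 1 adjusted over the list alone) and 7 rose and 0 fell in NC2b RNAi (8 adjusted over the list alone). The H3K9 methyltransferase gene G9a rose by 2.62 (SE 0.28) and 2.66 (SE 0.28), ash1 by 2.53 (SE 0.28) and 2.1 (SE 0.27), and Set2 by 2.19 (SE 0.31) and 1.89 (SE 0.30). Camera gave adjusted p = 0.000302 and 0.00084, and adjusted p = 0.707 and 0.724 with an estimated correlation. Of 7 dosage compensation genes 2 rose in each knockdown (2 and 3 adjusted over the list alone, and 1 fell so in NC2b RNAi), with msl-1 at 2.23 (SE 0.25) and 2.09 (SE 0.25). Of 21 genes of the ATAC and SAGA complexes and NC2, 4 rose in each and 1 fell in NC2b RNAi, with Ada2b at 1.89 (SE 0.20) and 1.90 (SE 0.20). Camera gave these lists adjusted p = 0.189 and 0.227, and 0.0954 and 0.198. Without hsbam 2, MSL3 RNAi library 1 or either NC2b RNAi library, 5 methylation genes passed in the libraries labelled MSL3 RNAi, and in NC2b RNAi 2 passed without hsbam 2. Of the ATAC, SAGA and NC2 genes 3 and 1 passed in NC2b RNAi without hsbam 1 or 2. Of the dosage compensation genes 1 passed without hsbam 2 in both knockdowns, 1 without hsbam 1 in NC2b RNAi, and 4 without MSL3 RNAi library 2 and 1 without either NC2b RNAi library in the libraries labelled MSL3 RNAi. Without either NC2b RNAi library 0 members of the lists in this and the next paragraph passed in NC2b RNAi by edgeR.

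Of 31 piRNA pathway genes 3 rose and 6 fell in the libraries labelled MSL3 RNAi, and 4 rose and 4 fell in NC2b RNAi, where 5 rose and 5 fell adjusted over the list alone. The Tudor-domain gene qin, antisense to CG14301, fell by 2.22 (SE 0.27) and 2.02 (SE 0.27). The list's medians were 0.10 and 0.26 and its means -0.21 and -0.04, and camera gave adjusted p = 0.430 and 0.985. Of 20 germline stem cell maintenance genes 5 rose and 1 fell in the first comparison and 6 rose in the second, with the BMP effector Mad at 1.29 (SE 0.20) and 1.24 (SE 0.20) (camera, adjusted p = 0.161 and 0.158). In the first comparison the piRNA genes passing numbered 3 without hsbam 2 and 2 without either NC2b RNAi library, and the maintenance genes 2 without hsbam 2 and 1 without MSL3 RNAi library 1 or either NC2b RNAi library. In the second they numbered 4 and 3 without hsbam 1 and 2 and 0 without hsbam 2. In NC2b RNAi the antimicrobial peptide genes CecA1 (5.19, SE 1.06), CecA2 (4.82, SE 0.83) and AttB (4.42, SE 0.93) rose, 3 of 23 members of their list, while TotA fell by 1.97 (SE 0.50), and without hsbam 1 or 2 the members passing numbered 2 and 0. In the RpS19b mutant 9 of 91 glutathione S-transferase and cytochrome P450 genes rose (20 rose and 1 fell adjusted over the list alone), with GstD3 at 1.78 (SE 0.21). Camera gave this list adjusted p = 4.88e-05, and adjusted p = 0.440 with an estimated correlation, and the 9 calls became 1 without either bam RNAi library and 26 without mutant library 1. The stress regulators p53 (-1.22, SE 0.18) and Corp (-1.51, SE 0.25) fell in the mutant, and Gadd45 (1.23, SE 0.23) rose. Their list of p53, apoptosis and ribosomal protein stress genes had a median of 0.24, so it did not fall as a whole.

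The lower RpS19b, ord, sunn, cona and hdm in the libraries labelled MSL3 RNAi and in NC2b RNAi were weighed against a technical reading, that control libraries 1 and 2 stand apart from the other hsbam libraries. The values argue against it, since 5 of the 5 genes were lower in all 4 knockdown libraries than in each of the 6 hsbam libraries outside the polysome fraction. A shift in stage stays open: a larger share of late-stage RNA lowers all early transcripts alike, and only 2 of the 5 genes, RpS19b and hdm, lay below the 5th percentile of 100 genes matched on level and on the ratio of whole ovary to bam RNAi in both comparisons. Neither of these 2 genes lay below it by more than its SE in both. Across genes, fold changes followed that ratio less in the libraries labelled MSL3 RNAi (r = 0.42) than in NC2b RNAi (r = 0.63). All 5 genes nevertheless fell further in the former, but the direct test of the knockdowns passed 0 genes by edgeR. Whole ovaries, with no RNAi, were low in these genes too. Their 1 library had 4.9 CPM of RpS19b, 1.89 of ord, 2.75 of sunn, 3.21 of cona and 0.761 of hdm. The highest values in the 4 knockdown libraries were 3.39, 12.4, 5.58, 4.83 and 0.35 CPM, so levels this low or nearly so occurred without a knockdown. For the 5 genes a stage shift and a dependence on the targeted gene therefore cannot be told apart. The different handling of bam in the control could also bring a stage shift. For c(3)G in the libraries labelled MSL3 RNAi the percentile among its matched genes was 0, with a fold change of -2.24 (SE 0.37) and a 5th percentile of -0.56. Its matched genes had a median of 0.35. In whole ovaries c(3)G had 187 CPM, against at most 71.5 CPM in the 4 libraries labelled MSL3 or NC2b RNAi. Against the same hsbam 1 and 2 it was -0.48 in Set2 RNAi, the libraries nearest to whole ovaries (r = 0.932 and 0.913). For c(3)G these values argue against a larger share of late-stage RNA as the sole cause. Both matchings rest on the single whole ovary library, and reads of antisense Uros2 could enter the count of c(3)G. Another shift in stage therefore stays open, and a dependence on the knockdown is not shown.

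The lower heat shock genes in Set2 RNAi were weighed against a heat shock response in the hsbam libraries of the same experiment. Against hsbam 3 and 4 the list's median was -3.15 in Set2 RNAi (16 of 18 lower), -3.02 in the libraries labelled MSL3 RNAi (17 of 18 lower) and -2.81 in NC2b RNAi (16 of 18 lower). Against hsbam 1 and 2, in which Hsp23 was 172 and 170 CPM, the medians were -1.33, -1.30 and -1.05. Libraries without Set2 RNAi were thus lower by similar medians against the same controls, and a response to the heat shock that induces bam may account for the lower values in Set2 RNAi. An effect of Set2 RNAi is not excluded, since these comparisons cross experiments. In total RNA of S19b RNAi the list's median was -2.49 (SD 1.59) against hsbam and -0.40 (SD 1.10) against bam RNAi.

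The higher muscle and fat body genes with the RpS19b mutation in bam RNAi were weighed against a reading of tissue content. If a lower share of germline RNA raised all other cell types alike, similar medians would follow. The lists did not rise alike in these libraries. The muscle median was 1.58 (SD 1.23) beside an early follicle cell median of 0.12 (SD 1.08), with permutation p = 4e-05 over 100000 draws, two-sided. The draws shuffled genes between lists, and genes of 1 tissue can move together, so this p does not measure the spread between libraries. Germline expression of the early follicle genes was not checked, so the difference does not settle this reading. Other lists outside the germline were higher too, with medians of 0.75 (SD 0.56) for escort, cap and terminal filament markers, 1.53 (SD 1.91) for yolk, vitelline membrane and chorion genes, 1.45 (SD 2.92) for antimicrobial and immune genes and 2.54 (SD 2.33) for fat body and hemocyte genes. The muscle median exceeded that of the escort list as well (permutation p = 0.00017) and was not shown to differ from those of the eggshell (p = 0.885) and antimicrobial lists (p = 0.501). A lower germline share, alone or in part, stays open. More muscle and fat body tissue in the mutant libraries and a change of expression within these tissues both stay open, since either would raise these genes and no test here separates them.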
